A study of Mus musculus with 6 samples.

How the data were processed

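RNA was measured in 6 libraries of primary bone marrow macrophages kept in macrophage colony-stimulating factor (M-CSF), 3 from wild-type (WT) mice and 3 from mice lacking RKIP (KO). Per the labels' protocols, total RNA went through oligo(dT) selection and the libraries were built with dUTP second-strand marking, which keeps the strand. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used, with no role or order given. The genome build was not given in the sources used here, and whether the counting used the strand was not given either. The genotype of each library was taken from its label.

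The deposited table held 27458 genes with FPKM (fragments scaled by transcript length and by library total) and an estimated count for each library, both made by the authors. The estimated counts had been rounded to whole numbers by the authors. Between libraries, the ratio of the count to the FPKM of a gene varied by at most 0.271% around a factor for each library (from the 1st to the 99th percentile, 7172 genes), so both values follow from the same coverage. Among low deposited estimated counts the value 4 was found 5769 times, against 3204 times for 3 and 2041 times for 5, and 8 was found 2692 times, against 1689 for 7 and 1204 for 9. About 4 counts therefore stood for 1 sequenced fragment, and a floor of 3 fragments, or 12 counts per library, was used for genes with a count of 0. Intervals and floors cover counting error only. Gene IDs matched the GENCODE M21 annotation of GRCm38 for 27382 genes, of which 24732 had identical coordinates and 27306 shared the chromosome and the start or the end. Coordinates are given as the deposited table lists them. Transcript length and GC content were those of the longest annotated transcript. No column of per-sample values was left out.

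Total estimated counts were 55255365, 53907941 and 53188659 in WT libraries 1 to 3 and 63607276, 67850358 and 70059042 in KO libraries 1 to 3. Counts of replicate libraries, divided by 4 to stand for fragments, differed by more than sampling noise (chi-square per degree of freedom from 3.86 to 8.00 over the 6 pairs), so each library was counted as 1 replicate. The labels do not say that the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical.

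KO was compared with WT by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the estimated counts, with TMM scaling, for the 11636 genes with a mean of at least 1 FPKM. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The test chosen before the data were examined was limma on log2(FPKM + 1), to be replaced by this one if the table held raw counts. The counts of the table are estimated and are not raw counts, and the rule was applied to them all the same, with limma kept as an alternative. The filter, the gene lists, the rule for named genes and most alternatives were also fixed before the data were examined. Named genes are Pebp1, the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, the 4 tested members of each list with the smallest p, kinases of the Raf cascade, and genes past the threshold within 10 Mb of Pebp1. Unnamed gene models, pseudogenes and mitochondrial genes were left out of the largest changes.

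The 37 gene lists cover osteoclast, activation, signalling, identity, metabolic and quality genes and markers of other bone marrow cells. Lists with at least 5 tested members, 35 in all, were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry. Adjustment was over the lists. Counts of members past the threshold are given over all tested genes and adjusted over the list alone.

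Processed pseudogenes were matched to coding transcripts with minimap2 2.31, at a cover of at least 50% of the pseudogene. Because fold changes followed transcript length, a correction was added: each library's trend on transcript length and GC content was fitted by loess (span 0.3) and entered as an offset in edgeR. Pathway enrichment used the KEGG terms of the deposited table with 15 to 400 tested members, with a one-sided hypergeometric test over the 4454 tested genes that have a term. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The alternatives tried were limma on FPKM with pseudocounts of 1, 0.5 and 0.1, DESeq2 1.42.0, other filters and scalings, other estimates of the spread, the replicate number as a block, counts divided by 4, totals without rRNA and mitochondrial genes, and leaving out each library in turn. Alternatives planned for limma were run with edgeR where it has the same option (filters, median-ratio scaling, block, robust spread, libraries left out) and with limma otherwise.

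The tests of single genes were tried on simulated counts for these 11636 genes, drawn at the measured means and totals, with 50 genes changed at each fold. The edgeR test recovered 58% of genes changed 1.25-fold, 74% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and called 6 of 11436 unchanged genes. With a simulated length trend, 642 unchanged genes were called without the correction and 9 with it. That trend was linear, on length alone and weaker than the measured difference between the genotypes. Camera was tried on simulated normal values of independent genes in place of counts. Of 20 lists with no shift, it called none at the adjusted threshold, and it called the shifted list. Correlation between genes was not simulated, so its effect on the camera calls was not covered. Pbp2 and Pebp4, relatives of Pebp1, were not analysed here.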

Results

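The transcriptome of bone marrow macrophages, cells grown out of mouse marrow under M-CSF, was measured by RNA sequencing in the presence and absence of RKIP. RKIP (Raf kinase inhibitor protein) is a cytosolic protein known to bind Raf kinases and is encoded by Pebp1. The design holds 3 WT and 3 KO libraries, all from M-CSF cultures, with 53188659 to 70059042 estimated counts each. The comparison asked which genes differ when macrophages form without RKIP, in a study of how RKIP directs macrophage differentiation. Values are means ± SD in FPKM over 3 libraries per group. Where a log2 fold change (KO over WT) carries a ±, it is an approximate standard error. It was worked back as the absolute log2 fold change over the square root of the F statistic of the test. At low counts it may understate the error. Fold changes come from the edgeR fit with its scaling and differ from the ratio of the FPKM means.

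Pebp1 RNA was absent from the knockout. Its level was 39.2, 33.2 and 39.0 FPKM in the WT libraries (37.2 ± 3.44, n = 3), while the count was 0 in all 3 KO libraries, at least 413-fold lower against a floor of 12 counts per library (edgeR quasi-likelihood test, adjusted p = 1.48e-10). Pebp1 has 2 matched pseudogenes, so its share of reads in WT is uncertain. It lies on the minus strand of chromosome 5 from 117282654 to 117287625. Among kinases of the Raf, MEK and ERK cascade, Braf rose 1.23-fold, from 2.94 ± 0.0660 to 3.76 ± 0.137 FPKM. Map2k1 stood at 26.6 ± 1.52 FPKM in WT and 26.7 ± 0.907 in KO and Mapk3 at 110.4 ± 3.71 FPKM in WT and 115 ± 4.54 in KO, neither of them past the threshold. With the length and GC correction the log2 fold change of Braf was 0.01 (edgeR, adjusted p = 0.919), while Mapk3 at 0.14 (adjusted p = 0.0120) passed the threshold.

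**Figure D1:**
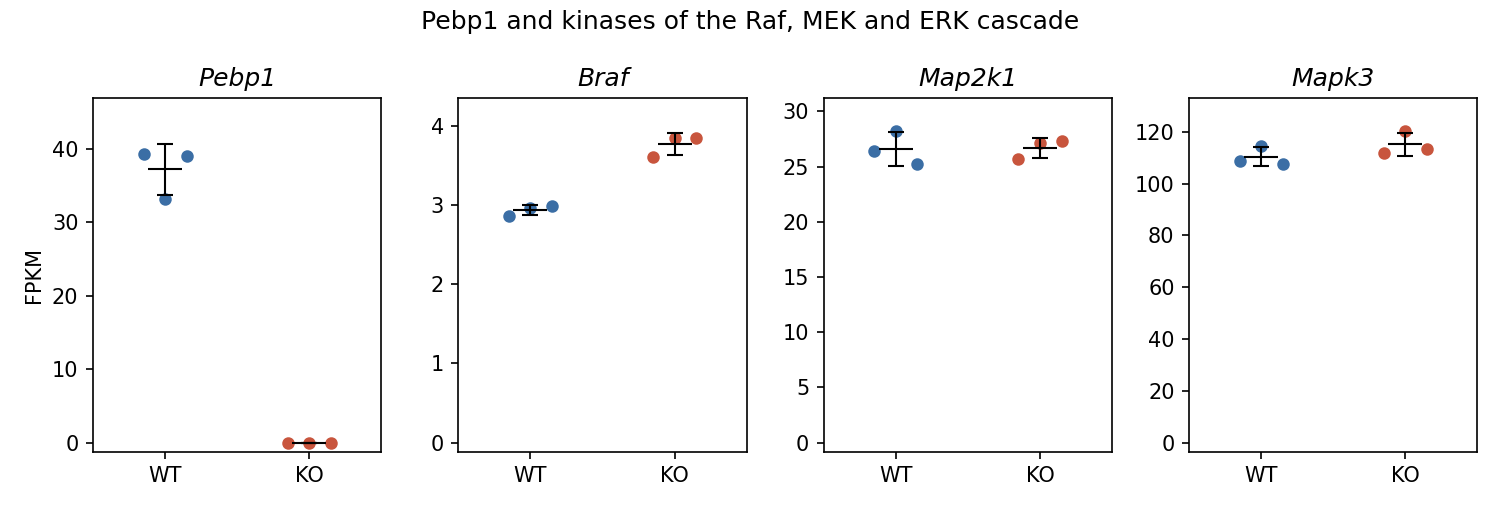
FPKM of Pebp1 and of 3 kinases of the Raf, MEK and ERK cascade in each library (points), with the group mean (long bar) and SD (whiskers), n = 3 per genotype, on linear axes that differ between genes. Pebp1 sits at 33.2 to 39.2 FPKM in WT and at 0 in every KO library.

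Genes of neutrophils were frequent among the largest falls, and Retnlg and Hal fell most after Pebp1. S100a9 and S100a8, the subunits of calprotectin, fell 75.8-fold and 48.7-fold, S100a9 from 57.0 ± 29.2 to 0.750 ± 0.234 FPKM. The granule proteins Ltf (36.7-fold, from 6.95 ± 0.0300 to 0.190 ± 0.00385 FPKM), Ngp (28.0-fold), Lcn2 (25.2-fold) and Camp (4.80-fold) fell with them. Retnlg, a resistin-like protein of neutrophils, fell from 11.2 ± 4.71 to 0.0863 ± 0.149 FPKM, with 302 fragments in the WT and 3 in the KO libraries, a ratio of 125 (95% exact Poisson interval 42.3 to 609). Hal, the enzyme that begins histidine breakdown, fell 78.1-fold, from 15.9 ± 0.148 to 0.210 ± 0.0623 FPKM. Slfn4 fell 19.9-fold, the chitinase-like gene Chil3 9.22-fold and the interleukin 33 receptor gene Il1rl1 5.13-fold. By the rule that selected them, each of these 11 genes was past the threshold and lower in all KO than in all WT libraries. The highest adjusted p among them was 0.00124, for Camp (edgeR quasi-likelihood test). S100a9, S100a8 and Retnlg were 23.3, 9.14 and 5.87 FPKM in WT library 1, against 72.1, 20.3 and 12.9 FPKM in WT library 2.

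The largest rise of a gene above 1 FPKM in both genotypes was that of Cebpb, a transcription factor of myeloid differentiation. It rose 4.63-fold, from 1.67 ± 0.240 to 8.07 ± 2.06 FPKM (log2 fold change 2.21 ± 0.18, edgeR, adjusted p = 6.61e-06). The immunoglobulin heavy chain genes Ighv3-6 (4.83-fold, from 0.452 ± 0.327 to 2.36 ± 0.313 FPKM) and Ighg1 (3.23-fold, from 1.18 ± 0.0755 to 3.96 ± 0.470 FPKM) rose, as did Clba1 (3.12-fold), which lies close to them on chromosome 12. Further rises were those of Limch1 (3.31-fold), Gcn1 (2.55-fold, an activator of the amino acid starvation kinase Gcn2), Esm1 (2.54-fold, from 6.83 ± 0.780 to 18.0 ± 1.39 FPKM), Chrdl1 (2.22-fold, a BMP antagonist), Gprc5c (2.08-fold), the inositol transporter gene Slc5a3 (1.96-fold) and the NK cell receptor gene Klra8 (1.93-fold). Tdg, a DNA glycosylase gene, was 3.60-fold higher, but its reads are uncertain: the pseudogene Tdg-ps2 moved the other way, from 15.3 to 2.35 CPM. Gcn1 has a matched pseudogene and lies beside Rplp0 near Pebp1 (below), so it is uncertain too.

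**Figure D2:**
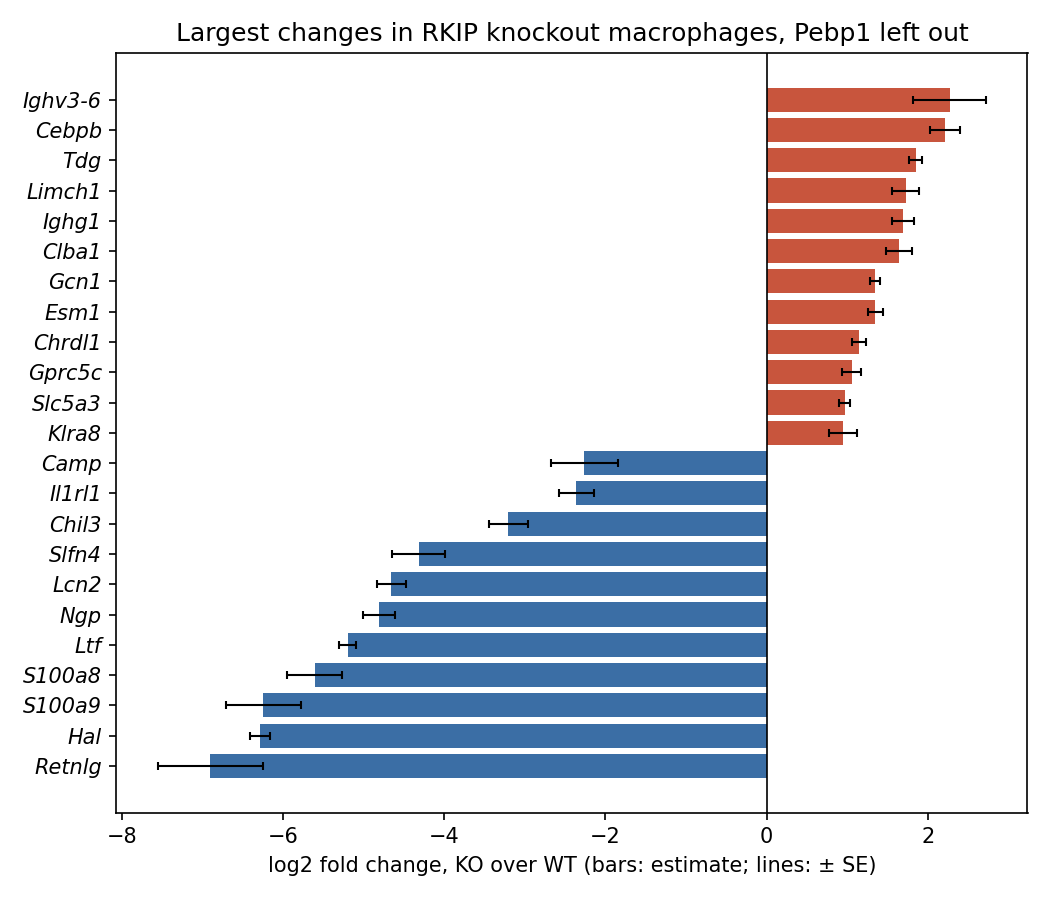
Log2 fold change, KO over WT (bars), for the 12 largest rises and the 11 largest falls after Pebp1. Values come from the edgeR fit of 3 WT and 3 KO libraries. Lines give an approximate standard error worked back from the F statistic of the test, which may understate the error at low counts. The rises reach 2.27 and the falls -6.90, the latter from a gene with 3 fragments over the KO libraries.

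Across all 11636 genes tested, 2364 were higher and 2253 lower in KO (edgeR quasi-likelihood test, adjusted p under 0.05), most of them by little. The median change of the called genes was 1.25-fold, and 33 higher and 230 lower genes changed at least 2-fold. Of protein-coding genes, 2284 were higher and 1854 lower. Pseudogenes went mostly down, with 22 higher and 363 lower of 826 tested and a median log2 fold change of -0.37, and they made up 160 of the 230 falls of at least 2-fold. With limma on log2(FPKM + 1), 2770 genes were higher and 1639 lower, a share of 62.8% higher against 51.2% in edgeR. Libraries of the same genotype correlated at r = 0.989 to 0.992 (log2 CPM, across genes) and those of different genotypes at 0.972 to 0.976.

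Short transcripts were lower and long ones higher in KO. In the shortest 10% of genes (38 to 966 bp) the median log2 fold change was -0.32, with 37 genes higher and 510 lower, and in the longest 10% (6575 to 40378 bp) it was 0.20, with 680 higher and 46 lower. Malat1, a long nuclear RNA, stood at 78.0 ± 10.7 FPKM in WT and 155 ± 18.2 in KO. Ribosomal RNA took 0.995 ± 0.237% of counts in WT and 1.64 ± 0.480% in KO, with overlap between the genotypes, and processed pseudogenes took 1.04 ± 0.0231% and 0.843 ± 0.0124%. With the length and GC correction, 1648 genes were higher and 1893 lower, and 1302 and 1384 of these were the same genes as without it. Of the corrected calls, 37 higher and 151 lower genes changed at least 2-fold.

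**Figure D3:**
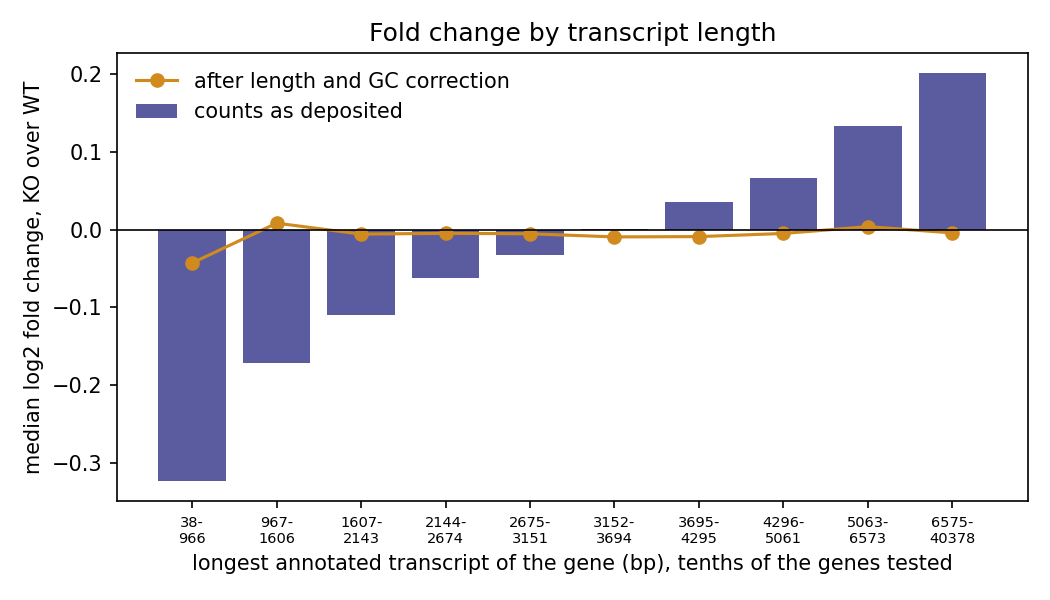
Median log2 fold change, KO over WT, in 10 groups of the tested genes ordered by the length of their longest annotated transcript (bp), from the counts as deposited (bars) and after the length and GC correction (points). The medians run from -0.32 in the shortest to 0.20 in the longest group, and with the correction they lie between -0.04 and 0.01.

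The neutrophil and the monocyte lists fell as groups. Of 13 tested neutrophil genes, 11 fell, with a median log2 fold change of -2.26 (camera, adjusted p = 8.67e-08, and adjusted p = 0.351 with an estimated correlation; 1 and 11 adjusted over the list alone for higher and lower). Beside the granule genes, Mmp9, the gelatinase of neutrophils and osteoclasts, fell 4.27-fold, from 16.5 ± 1.48 to 3.999 ± 0.648 FPKM. Among 20 monocyte genes, 11 fell and 3 rose (camera, adjusted p = 0.00887, and adjusted p = 0.351 with an estimated correlation, 3 and 11 adjusted over the list alone). Of this list, F13a1 fell from 23.5 ± 0.663 to 16.2 ± 0.465 FPKM, Cd177 from 1.62 ± 0.0662 to 0.439 ± 0.159 FPKM and Chil3 9.22-fold (above). Ccr2, the receptor for the monocyte attractant Ccl2, rose from 3.95 ± 0.336 to 6.79 ± 0.647 FPKM. Whether the members of the list, Cd177 and Chil3 among them, are particular to monocytes in these cultures was not tested. Their fall is therefore not counted as separate from that of the neutrophil genes. The short median length of the neutrophil genes, 1674 bp, places them among shorter transcripts, and their median log2 fold change with the length and GC correction was -2.04.

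Among markers of other marrow cells, no list beyond neutrophils and monocytes passed camera, while single genes changed. By fry the B cell and dendritic cell lists tested higher (adjusted p = 0.0294 and 0.0384). The T and NK cell and the mast cell and basophil lists had too few tested members for a test. Of B cell genes, 2 of 6 rose and 1 fell (2 and 2 adjusted over the list alone; camera, adjusted p = 0.436). Ighm, the heavy chain of IgM, rose from 22.5 ± 2.49 to 41.8 ± 3.96 FPKM and Ebf1 rose 1.31-fold, Cd22 fell 1.67-fold, and Blnk stood at 15.3 ± 0.305 FPKM in WT and 14.8 ± 0.339 in KO. Of dendritic cell genes, 2 of 7 rose and 1 fell (2 and 1 adjusted over the list alone; camera, adjusted p = 0.795). Itgax and Tcf4 rose (1.43-fold and 1.27-fold), Bst2 fell (1.36-fold) and Fscn1 stood at 32.9 ± 1.40 FPKM in WT and 30.9 ± 3.47 in KO. Of T and NK cell genes, 2 of 3 rose and 0 fell (2 and 0 adjusted over the list alone). Cd28 (1.61-fold) and Il7r (1.27-fold) were higher and Cd4 stood at 1.53 ± 0.194 FPKM in WT and 1.39 ± 0.115 in KO. Both tested mast cell and basophil genes, Il1rl1 (above) and Mcpt8 (2.02 ± 0.316 FPKM in WT and 1.53 ± 0.146 in KO), had lower means in KO, 1 of them past the threshold over all genes and 2 adjusted over the list alone. Of erythroid and megakaryocyte genes, 1 of 5 rose and 1 fell (2 and 1 adjusted over the list alone; camera, adjusted p = 0.593). Pf4 rose (1.21-fold) and Vwf fell (1.39-fold), a call that ended in limma on log2(FPKM + 1) (adjusted p = 0.0509). Epor stood at 0.994 ± 0.314 FPKM in WT and 1.55 ± 0.127 in KO and Treml1 at 0.960 ± 0.480 FPKM in WT and 1.20 ± 0.137 in KO. Of stromal and osteoblast genes, 4 of 24 rose and 6 fell (4 and 6 adjusted over the list alone; camera, adjusted p = 0.510). Cxcl12 rose from 87.7 ± 2.32 to 135 ± 5.17 FPKM and Igfbp7 and Lpl rose 1.35-fold and 1.41-fold, while Spp1, the matrix protein osteopontin, fell from 1439.9 ± 163 to 950.2 ± 32.2 FPKM. The calls of Tcf4, Bst2 and Il7r ended with the length and GC correction, at log2 fold changes of 0.04, -0.15 and 0.21 (edgeR, adjusted p = 0.515, 0.235 and 0.0842). Blnk, as lower, and Epor, as higher, passed with it, at -0.19 and 0.71 (edgeR, adjusted p = 0.00219 and 0.0386). With the correction the B cell counts were 3 higher and 2 lower. Treml1 passed without WT library 1 (log2 fold change 0.75, edgeR, adjusted p = 0.0375).

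Osteoclast genes split into members that fell and members that rose. Of 25 tested, 7 fell and 9 rose (10 and 8 adjusted over the list alone for higher and lower), with a median log2 fold change of 0.03 (camera, adjusted p = 0.874). Mmp9, which is also in the neutrophil list, fell 4.27-fold, Acp5, which encodes TRAP, 3.76-fold (from 18.9 ± 2.55 to 5.20 ± 0.661 FPKM), and Ctsk, the collagenase cathepsin K, 1.80-fold (from 22.1 ± 0.369 to 12.8 ± 0.0858 FPKM). Atp6v0d2, a proton pump subunit needed for cell fusion, rose from 14.6 ± 0.975 to 24.3 ± 1.07 FPKM. Receptor and adaptor genes of M-CSF and RANK signalling rose, 13 of 26 against 1 that fell (camera, adjusted p = 0.00281, and adjusted p = 0.455 with an estimated correlation; 15 and 2 adjusted over the list alone), among them Csf1r (from 298 ± 2.19 to 381 ± 15.4 FPKM), Tnfrsf11a, which encodes RANK (from 8.30 ± 0.0919 to 10.9 ± 0.128 FPKM), Il6ra (1.31-fold) and Pik3cg (1.29-fold).

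Genes that hold osteoclast formation back, and factors that act on osteoblasts, also went both ways. Of osteoclast inhibitors, 4 of 17 rose and 3 fell (4 and 4 adjusted over the list alone; camera, adjusted p = 0.821). Cyld rose 1.32-fold and Tnfrsf11b, which encodes the RANKL decoy osteoprotegerin, rose from 17.8 ± 1.09 to 23.2 ± 0.657 FPKM, whereas Nr1h3 and Bcl6 fell 1.45-fold and 1.18-fold. Of coupling factors, 3 of 18 rose and 6 fell (4 and 6 adjusted over the list alone; camera, adjusted p = 0.624). Igf1 rose from 80.1 ± 3.38 to 111 ± 6.46 FPKM, and C3 (1.47-fold), Tnf (1.70-fold) and Spp1 fell. With the length and GC correction the log2 fold change of Igf1 shrank from 0.42 to 0.09 (edgeR, adjusted p = 0.0367). The call of Bcl6 ended without WT library 3 (edgeR, adjusted p = 0.0523) and in limma on log2(FPKM + 1) (0.0549). By fry the osteoclast list tested lower (adjusted p = 0.0259), opposite in sign to its median.

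**Figure D4:**
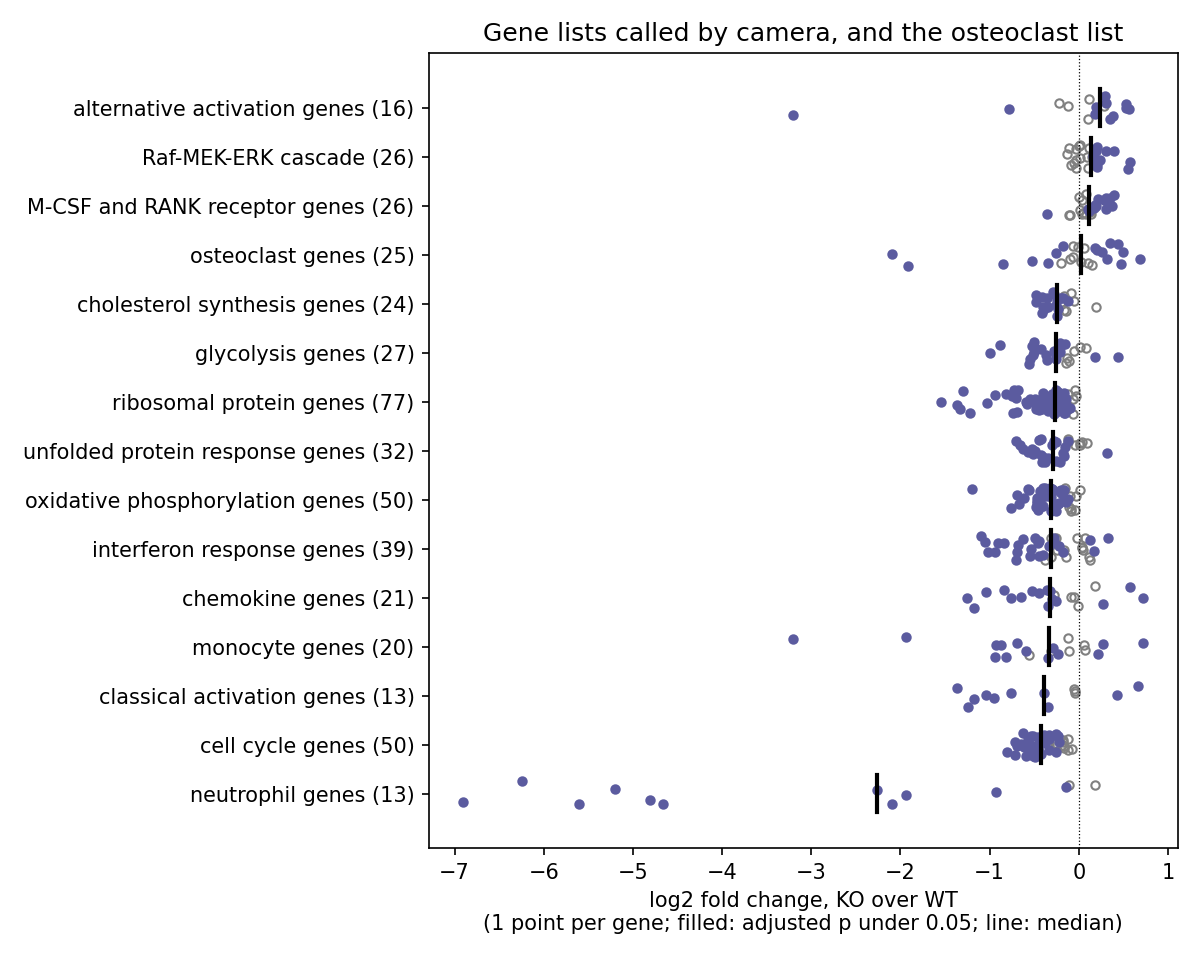
Log2 fold change, KO over WT, of each tested member (1 point per gene, filled where adjusted p is under 0.05 by edgeR) of the 14 lists called by camera with its preset correlation and of the osteoclast list, with the list median (line) and the number tested in brackets. The neutrophil list lies lowest, at a median of -2.26, and the alternative activation list highest, at 0.24.

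Genes of classical activation were lower and several genes of alternative activation higher in KO. Of 13 classical activation genes, 8 fell and 2 rose (camera, adjusted p = 0.0189, and adjusted p = 0.449 with an estimated correlation, 2 and 8 adjusted over the list alone). The scavenger receptor gene Marco fell from 366 ± 16.6 to 197 ± 6.35 FPKM, Acod1, which makes itaconate, from 2.14 ± 0.240 to 0.859 ± 0.0782 FPKM, and the formyl peptide receptor gene Fpr2 2.37-fold, while the arginine transporter gene Slc7a2 rose 1.58-fold. Of 16 alternative activation genes, 9 rose and 2 fell (camera, adjusted p = 0.0481, and adjusted p = 0.449 with an estimated correlation, 10 and 2 adjusted over the list alone). The mannose receptor gene Mrc1 rose from 413 ± 15.7 to 631 ± 17.4 FPKM and Cd36 from 352 ± 21.3 to 464 ± 20.8 FPKM, and Chil3 (above) and Tgm2 (1.72-fold) fell. The call of this list ended without WT library 3 or without any 1 of the KO libraries (camera, adjusted p from 0.0516 to 0.113), with quantile normalization (0.0718) and with a pseudocount of 0.1 on FPKM (0.0992). Fpr2 has a matched pseudogene in the table, so its share of reads is uncertain.

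Interferon and chemokine genes fell. Of 39 interferon response genes, 22 fell and 3 rose (camera, adjusted p = 0.00230, and adjusted p = 0.675 with an estimated correlation, 3 and 24 adjusted over the list alone), with a median log2 fold change of -0.32. The ubiquitin-like modifier gene Isg15 fell from 21.3 ± 3.96 to 10.4 ± 2.05 FPKM, Usp18, which removes that modifier, 2.02-fold, the nucleic acid sensor gene Zbp1 1.92-fold, and Ifi27l2a from 172 ± 34.9 to 111 ± 4.24 FPKM. By fry this list did not pass (adjusted p = 0.0848). Of 21 chemokine and receptor genes, 13 fell and 3 rose (camera, adjusted p = 0.0181, and adjusted p = 0.496 with an estimated correlation, 3 and 13 adjusted over the list alone). Ccl2 fell from 18.6 ± 2.00 to 10.8 ± 1.22 FPKM, Ccl6 from 130.1 ± 8.86 to 86.5 ± 5.30 FPKM and Ccl4 from 6.13 ± 0.535 to 2.66 ± 0.661 FPKM, whereas Cxcl12 and Ccr2 rose (above). A pseudogene matches Isg15, so its share of reads is uncertain.

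The other immune lists passed no camera test. By fry the NF-kB and MHC class II lists tested lower (adjusted p = 0.0294 and 0.0389) and the Toll-like receptor list higher (adjusted p = 0.0457). Of NF-kB targets, 4 of 25 rose and 8 fell (4 and 8 adjusted over the list alone; camera, adjusted p = 0.319). Bcl2a1b fell from 28.8 ± 2.67 to 18.2 ± 1.02 FPKM, Ccl2 and Ccl4 fell, and Cflar, an inhibitor of caspase 8, rose 1.20-fold. Of Toll-like receptor pathway genes, 7 of 28 rose and 2 fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.231). Tlr4 rose from 14.6 ± 0.159 to 20.4 ± 1.98 FPKM, Tlr7 1.29-fold, Tlr8 1.31-fold and the adaptor gene Ticam2 1.19-fold. Of 7 genes of MHC class II presentation, 4 fell (4 adjusted over the list alone), namely the invariant chain gene Cd74 (from 11.6 ± 1.31 to 7.56 ± 1.51 FPKM), Ctss (1.28-fold), H2-Ab1 (1.53-fold) and H2-DMa (1.24-fold), and the list did not pass (camera, adjusted p = 0.128). With the length and GC correction the calls of H2-Ab1, H2-DMa and Cflar ended (edgeR, adjusted p = 0.0884, 0.151 and 0.163). The call of H2-Ab1 also ended without WT library 3 (0.0559), and that of H2-DMa without WT library 1 (0.112), KO library 1 (0.0526) or KO library 3 (0.101) and in limma on log2(FPKM + 1) (0.0757). A pseudogene matches Cflar, which leaves its value uncertain.

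Components of the Raf, MEK and ERK cascade rose slightly, while more of the genes that ERK activity induces fell than rose. Of 26 cascade genes, 11 rose (camera, adjusted p = 0.0151, and adjusted p = 0.455 with an estimated correlation; 12 and 1 adjusted over the list alone for higher and lower), with a median log2 fold change of 0.13. Among them were Nf1 (from 4.15 ± 0.129 to 6.33 ± 0.457 FPKM) and Rasa1 (from 11.2 ± 0.784 to 17.3 ± 1.09 FPKM), whose proteins switch Ras off, and Sos1 (1.31-fold), a Ras exchange factor. With the length and GC correction the call of the list ended (adjusted p = 0.0931, median 0.05), as did that of Sos1 (log2 fold change 0.09, edgeR, adjusted p = 0.198). Of ERK response genes, 3 of 26 rose and 10 fell (3 and 10 adjusted over the list alone; camera, adjusted p = 0.185). By fry this list tested lower (adjusted p = 0.0406). The immediate early genes Fos and Junb fell from 5.04 ± 0.301 to 3.42 ± 0.342 FPKM and from 27.8 ± 0.568 to 21.6 ± 0.796 FPKM, and Spred1, a feedback inhibitor of the pathway, rose from 20.8 ± 0.276 to 29.6 ± 0.390 FPKM. Etv1 rose 1.299-fold, a call that ended with the length and GC correction (log2 fold change 0.09, edgeR, adjusted p = 0.151). A pseudogene matches Etv1, so its share of reads is uncertain.

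Core macrophage genes stayed abundant in both genotypes and moved in both directions. Of macrophage identity genes, 9 of 30 rose and 9 fell (10 and 9 adjusted over the list alone; camera, adjusted p = 0.587). Adgre1, which encodes F4/80, rose from 288 ± 5.19 to 382 ± 7.79 FPKM, the transcription factor genes Maf and Cebpa rose from 56.3 ± 1.05 to 87.9 ± 1.88 FPKM and from 39.4 ± 1.74 to 59.4 ± 4.44 FPKM, and the complement gene C1qa fell from 716 ± 24.5 to 584 ± 7.49 FPKM. Of genes of bone marrow resident macrophages, 5 of 16 rose and 6 fell (6 and 7 adjusted over the list alone; camera, adjusted p = 0.669). The iron exporter gene Slc40a1 rose from 50.2 ± 1.34 to 90.6 ± 1.77 FPKM, the transferrin gene Trf rose 1.39-fold, and the receptor kinase gene Axl fell from 26.8 ± 0.263 to 18.4 ± 0.572 FPKM. Of phagocytosis and Fc receptor genes, 10 of 30 rose and 9 fell (10 and 10 adjusted over the list alone; camera, adjusted p = 0.940). Mrc1 rose, and Marco, Axl and the adaptor gene Tyrobp (1.44-fold) fell. Of adhesion and matrix genes, 9 of 38 rose and 12 fell (10 and 12 adjusted over the list alone; camera, adjusted p = 0.610). The proteases Mmp9, Mmp8 (from 8.60 ± 0.282 to 4.69 ± 0.270 FPKM) and Adam8 (1.40-fold) and the matrix gene Spp1 were among those that fell.

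Genes of proliferation were lower in KO. Of 50 cell cycle genes, 39 fell (camera, adjusted p = 1.70e-12, and adjusted p = 0.412 with an estimated correlation, 44 lower adjusted over the list alone), at a median log2 fold change of -0.42. The mitotic kinase gene Plk1 fell from 16.3 ± 0.570 to 10.7 ± 0.651 FPKM, the replicative helicase genes Mcm5 and Mcm3 from 11.7 ± 0.773 to 8.16 ± 0.141 FPKM and from 14.4 ± 0.557 to 10.4 ± 0.608 FPKM, and Gins2, of the same helicase, 1.61-fold. With the length and GC correction 44 members were lower. Of p53 targets, 7 of 24 rose and 4 fell (7 and 4 adjusted over the list alone; camera, adjusted p = 0.593). Trp53inp1 rose from 21.02 ± 1.15 to 32.6 ± 1.79 FPKM, Zmat3 1.27-fold, Rrm2b 1.39-fold and Ccng1 1.17-fold. Plk1 and Rrm2b have a matched pseudogene and are uncertain in this respect.

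Metabolic genes fell in several lists. Of 27 glycolysis genes, 19 fell and 2 rose (camera, adjusted p = 1.59e-06, and adjusted p = 0.391 with an estimated correlation, 2 and 21 adjusted over the list alone), with Pkm lower (from 349 ± 7.65 to 248 ± 2.38 FPKM), Eno1 lower (from 104 ± 3.38 to 75.1 ± 0.395 FPKM) and the lactate exporter gene Slc16a3 lower (1.85-fold). Gapdh fell 1.99-fold in the table, but 48 pseudogenes match it there and its share of reads is uncertain, as are those of Pkm, Fdps and Fdft1, which have matched pseudogenes too. Of 24 cholesterol synthesis genes, 17 fell (camera, adjusted p = 1.16e-05, and adjusted p = 0.412 with an estimated correlation, 1 and 20 adjusted over the list alone), among them Sqle (from 12.1 ± 0.746 to 9.82 ± 0.0764 FPKM), Fdft1 (1.40-fold), Fdps (1.39-fold) and Lss (1.33-fold). Of lipid handling and cholesterol efflux genes, 4 of 24 rose and 8 fell (4 and 8 adjusted over the list alone; camera, adjusted p = 0.592). The cholesterol exporter gene Abca1 rose from 51.9 ± 2.82 to 83.5 ± 3.14 FPKM and Lpl rose, and Plin2 (1.304-fold) and Gpnmb (1.21-fold) fell.

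Nuclear genes of the respiratory chain and ribosomal protein genes fell, and both groups are short. Of 50 oxidative phosphorylation genes, 42 fell (camera, adjusted p = 2.22e-12, and adjusted p = 0.439 with an estimated correlation; 42 lower adjusted over the list alone), among them Atp5g3 (from 35.2 ± 1.38 to 24.8 ± 0.824 FPKM), Ndufa3 (from 10.5 ± 0.781 to 4.77 ± 0.172 FPKM), Cox7b (1.59-fold) and Cox6b1 (1.39-fold). Of 77 ribosomal protein genes, 67 fell (camera, adjusted p = 8.79e-15, and adjusted p = 0.455 with an estimated correlation; 71 lower adjusted over the list alone), among them Rplp0 (from 661 ± 27.8 to 279 ± 10.5 FPKM), Rps28 (2.34-fold), Rps29 (2.58-fold) and Rps19 (2.93-fold). A pseudogene matches 72 of the ribosomal protein genes, so the values of single members are uncertain, as is that of Cox7b. Median lengths were 1232 and 1094 bp, and with the length and GC correction the median log2 fold changes moved from -0.32 to -0.14 and from -0.27 to -0.12, with 23 respiratory genes lower, and 35 ribosomal protein genes lower and 5 higher. Of 13 genes encoded by mitochondrial DNA, only mt-Co3 passed (1.13-fold lower, none adjusted over the list alone), and mt-Nd4, mt-Nd3 and mt-Nd4l had log2 fold changes of 0.16 ± 0.06, -0.21 ± 0.10 and -0.09 ± 0.06 (camera, adjusted p = 0.894). The call of mt-Co3 ended in limma, with the length and GC correction, and without each library except WT library 3, while with the correction mt-Nd3 passed as lower and mt-Nd4l as higher (-0.19 and 0.14, edgeR, adjusted p = 0.0358 and 0.0159).

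Genes of the unfolded protein response fell, whereas oxidative stress and lysosome genes went both ways. Of 32 genes of the unfolded protein response, 24 fell and 1 rose (camera, adjusted p = 4.17e-07, and adjusted p = 0.351 with an estimated correlation, 1 and 24 adjusted over the list alone). Calr fell from 414 ± 10.5 to 322 ± 12.8 FPKM, Pdia6 from 81.3 ± 0.651 to 61.9 ± 2.54 FPKM, Sdf2l1 1.49-fold and the stress transcription factor gene Atf4 from 40.2 ± 0.844 to 31.2 ± 1.19 FPKM. Of heat shock genes, 2 of 20 rose and 10 fell (2 and 11 adjusted over the list alone; camera, adjusted p = 0.0922). Hspe1 (1.43-fold) and Hspd1 (1.17-fold) fell, and Dnajb4 (1.28-fold) and Chordc1 (1.20-fold) rose. With the length and GC correction the heat shock list passed as lower (camera, adjusted p = 0.0116). The log2 fold change of Chordc1 turned to -0.08 with that correction. Of oxidative stress and iron genes, 5 of 29 rose and 14 fell (6 and 17 adjusted over the list alone; camera, adjusted p = 0.231). The catalase gene Cat rose from 414 ± 7.39 to 505 ± 11.7 FPKM and Slc40a1 rose, and Gpx1 (from 118 ± 11.2 to 86.9 ± 2.31 FPKM) and Gsta3 (1.43-fold) fell. Of lysosome genes, 8 of 43 rose and 14 fell (11 and 16 adjusted over the list alone; camera, adjusted p = 0.448). Scarb2 (1.25-fold) and Ctsc (1.18-fold) rose, and Ctss (1.28-fold) and Atp6v0c (1.24-fold) fell. Of the genes named here, Calr, Hspe1, Hspd1 and Atp6v0c have a matched pseudogene and their shares of reads are uncertain.

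Near Pebp1 on chromosome 5, genes changed about as often as elsewhere. Within 10 Mb, 74 of 184 tested genes passed the threshold (40.2%, against 39.7% elsewhere), 33 higher and 41 lower. The named genes that rose, from the largest change down, were Gcn1, Acad12, Ttc28, Chek2, Rpap2, Ift81, Tmed5, Ankrd13a, Dr1, Ssh1, Sppl3, Tgfbr3, Sbno1, Evi5, Ube3b, Fbrsl1, Ankle2, Med13l, Git2, P2rx7, Setd1b, Mlxip, Acad10, Ulk1, Sh2b3, Tpcn1, Idua, Zfp664, Fbxo21, Rab35, Clip1 and P2rx4. Those that fell included, again from the largest, Atp5k, Rplp0, Alkbh2, Pop5, Rpl37rt, Pole, Oas1g, Grk3, Oas3, Oas1a, Vsig10, Mmab, Dynll1, Cox6a1, Aacs, Gltp, Hspb8, Crlf2, Noc4l, Kntc1, Coq5, Oasl2, Cdk2ap1, Kmt5a, Ddx51, Oas2, Selplg, Arl6ip4, Pus1, Pgam5, Bri3bp, Vps29, Naa25, Pxn, Rpl6, Anapc5, Scarb1 and Ddx54. Of these, Evi5, Sppl3, Gcn1, Dynll1, Anapc5, Rpl6, Kmt5a, Atp5k and Rplp0 have matched pseudogenes, and their values are uncertain. Gcn1, Rplp0 and Atp5k changed at least 2-fold, 3 of the 179 tested genes there that are not pseudogenes (1.68%, against 0.837% elsewhere, Fisher's exact test, two-sided p = 0.196). Rplp0 (115559467 to 115563727) and Gcn1 (115565254 to 115622654) lie side by side. They moved in opposite directions, at log2 fold changes of -1.30 and 1.35, so the 2 changes may not be separate.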

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

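DESeq2, counts divided by 4, totals without rRNA and mitochondrial genes and the length and GC correction, with and without a block, were chosen after the result was seen. The limma test on log2(FPKM + 1) was the planned test for a table without counts, and the other settings were planned as changes to it. Counts of genes past the threshold stayed within 1.5 times of 2364 higher and 2253 lower under the other scalings, filters, tests and spread estimates, from 1597 to 2784 higher and from 1589 to 2343 lower. A further bound of 2-fold left 33 higher and 230 lower, fewer by its construction. Leaving out 1 library gave 1969 to 2272 higher and 1794 to 2047 lower genes. The share of called genes that were higher was 62.8% in limma on FPKM, 62.9% with a pseudocount of 0.1 and 61.3% after rescaling to equal sums. It was 63.5% without the trend, 61.9% with library weights and 57.2% with quantile normalization, against 51.2% in the main edgeR test. The share thus moved with the scaling of the libraries, and the cause was not tested. Pebp1 stayed lower and past the threshold under each setting.

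The length and GC correction moved named genes most: 135 kept direction and side of the threshold, 10 fell short of it, 5 passed it and 2 reversed. Chordc1 turned to -0.08249 and mt-Nd4l to 0.1407, and with the replicate block added they stood at -0.08195 and 0.1416. Calls that held could still change in size. The log2 fold change of Ifi27l2a went from -0.69 to -0.305 and that of Cox6b1 from -0.47 to -0.13, while that of Pf4 grew from 0.27 to 0.60. Leaving out 1 library let Fscn1 (without KO library 2), mt-Nd3 (KO library 1), mt-Nd4 (WT library 1) and Epor (WT library 2) pass. Keeping all genes ended the calls of Bst2, H2-Ab1, H2-DMa and mt-Co3, and limma on log2(FPKM + 1) those of Bcl6, H2-DMa, Vwf and mt-Co3. With the estimated correlation camera called 0 of 14 lists (lowest adjusted p 0.35, 4 lists at an unadjusted p under 0.05), while fry, which compares a list with no other genes, called 27. By fry the osteoclast list turned from 1 to -1 (1 for higher, -1 for lower). The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.023, 0.19 and -0.038, and WT library 1 correlated best with KO library 3 (0.16). With the replicate block 2407 genes were higher and 2294 lower, and 14 lists were called. Genes with few fragments limit the depth: the pseudocounts of limma shrank the folds of Retnlg, Slfn4, Lcn2 and Il1rl1. A 1.25-fold change was recovered for 58% of simulated genes, in a simulation with far fewer changed genes than were called here.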

Other observations

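The pathway enrichment and each test of an explanation in this part, except that of GC content, were chosen after the result was seen. By the KEGG terms of the deposited table, 10 of 274 pathways held more of the lower genes than chance gives with and without the length and GC correction. Proteasome genes were among them, with 36 of 44 tested genes lower (hypergeometric test, one-sided, adjusted p = 1.75e-14, and 25 lower with the correction, adjusted p = 1.3e-05). Its catalytic subunit gene Psmb5 went from 56.6 ± 2.17 to 31.2 ± 0.815 FPKM, the regulatory subunit gene Psmd8 from 61.5 ± 1.93 to 49.5 ± 1.40 FPKM and the assembly chaperone gene Pomp from 11.1 ± 0.932 to 8.58 ± 0.472 FPKM. One-carbon metabolism by folate, which supplies nucleotide synthesis, had 10 of 16 genes lower (adjusted p = 0.0185), among them Shmt2 (1.34-fold), Mthfd2 (1.41-fold) and Tyms (1.48-fold). Ribosome biogenesis had 27 of 70 lower (adjusted p = 0.0409), among them the fibrillarin gene Fbl (from 10.3 ± 0.648 to 7.27 ± 0.0986 FPKM) and Nop10 (1.74-fold). These genes were chosen after their values were seen, and Psmb5, Shmt2, Tyms and Fbl have a matched pseudogene that leaves their values uncertain.

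Among higher genes, 24 pathways passed with and without the correction. MAPK signalling had 69 of 198 tested genes higher (hypergeometric test, one-sided, adjusted p = 0.000101, and 56 higher with the correction, adjusted p = 0.000379), and 23 lower. Its members include Kitl, the ligand of the receptor Kit (from 14.3 ± 0.515 to 26.6 ± 1.67 FPKM), and the transcription factor gene Mef2c (from 4.75 ± 0.220 to 8.62 ± 0.618 FPKM), both chosen after their values were seen. Regulation of the actin cytoskeleton had 54 of 152 higher (adjusted p = 0.000384) and 22 lower, with the thrombin receptor gene F2r (from 5.53 ± 0.218 to 9.54 ± 0.582 FPKM) and Rock1 (1.48-fold) among the higher. Osteoclast differentiation had 33 of 107 higher (adjusted p = 0.031, and 30 with the correction, adjusted p = 0.0166), among them Nfatc2 (from 6.84 ± 0.323 to 10.05 ± 0.390 FPKM), Mitf (1.35-fold) and Tnfrsf11a, while 25 were lower (20 with the correction), Acp5 and Ctsk among them. The osteoclast list of the report passed no camera test (adjusted p = 0.874). The hypergeometric test treats genes as independent, which they are not.

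Of 13 tested neutrophil genes, 6 kept under 10% of their WT level in KO, and neutrophils left in the WT cultures are a candidate source: the labels name no sort, and S100a9 stood at 57.0 FPKM, Ngp at 24.8 and S100a8 at 16.8 in WT. The length and GC trend is argued against, with the list at a median of -2.04 after its correction against -2.26 before. Of all tested list members, 5 reached 1 FPKM in KO and 4 stand in another list, none of them among the 6. An admixture of fixed make-up would keep 1 ratio between WT libraries: over the 6 genes the ratio of WT library 1 to the others ran 3.19 times apart (lower 95% bound 2.62), but that of WT library 2 to WT library 3 only 1.14 times (lower bound 0.856), so the departure rests on 1 library and excludes nothing. Left-over neutrophils cannot be told apart from a change in the cells with genotype, which stays open and untested.

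The dependence of fold change on transcript length could come from the libraries or from the cells. Over 11627 genes the Spearman correlation of log2 fold change with length was 0.492 (across genes, which are not independent replicates). Reads shared with processed pseudogenes do not account for it, since it was 0.439 without pseudogenes and their parents, and GC content does not either, with a median of 0.505 over all GC bins (0.354 to 0.54). The slope per doubling of length was -0.09, -0.06 and -0.06 in the WT and 0.05, 0.07 and 0.08 in the KO libraries, a difference between genotypes of 0.14 with a range within a genotype of at most 0.0304. A library batch or size selection that followed genotype cannot be told apart from an effect of genotype, because every library of a genotype lies on the same side.

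Some parent genes and their processed pseudogenes moved in opposite directions: Rplp0 fell while Gm8730, Gm14165 and Gm9625 together rose from 65.2 to 521 CPM, and Rps19, Psmb5 and Tdg each had such a partner. Reads that change place between near-identical copies may explain this, since the median absolute log2 ratio of the summed families was 0.439 against 1.42 for the parents, although a sum of members that move apart must change less than the parent. A sequence variant in the knockout strain could shift reads in this way. Of the parents Tdg, Rps19 and Psmb5, 0 lie within 10 Mb of Pebp1. They are on chromosomes 10, 7 and 14, which places these 3 parents outside donor sequence around Pebp1. This is a fact of position and not a test, because the 3 parents were set apart from Rplp0 after the result was seen. The positions of their partner pseudogenes were not checked, so donor sequence there stays open. Rplp0 lies 1.72 Mb away, and for it and for Gcn1 beside it the question of donor sequence stays open. Variants elsewhere in the genome stay open too and were not tested. No biological explanation was tested.

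Gm9824 and Gm10819, pseudogenes matched to Pebp1 on chromosomes 10 and 19, were at 18.6 ± 7.60 and 9.01 ± 1.17 FPKM in WT and had a count of 0 in each KO library, at least 65.7-fold and 31.8-fold lower against 12 counts per library. Reads of Pebp1 and of these matched copies were not told apart here, so their falls are not counted as separate from that of Pebp1. Gm8543, on chromosome 9 and matched to Actg1, went from 2.17 ± 0.310 FPKM to a count of 0 in each KO library as well, at least 15.5-fold lower. Of the 12 largest rises, Clba1, Ighg1 and Ighv3-6 lie within 1.48 Mb of chromosome 12 (112808937 to 114288582), where 18 genes were tested, 6 were higher, 3 lower and 4 changed at least 2-fold. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05: the split by genotype gave 4617 called genes, 1 split in all gave as many, and the highest other split gave 1.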
